A study of Rattus norvegicus with 12 samples.

How the data were processed

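Liver RNA of 12 male diet-induced obese Sprague-Dawley rats was measured on Affymetrix Rat Gene 1.0 ST arrays, 1 array per liver sample, with 4 samples for each of 3 diets (casein, complete dairy, and casein with added leucine). Per the labels' protocols, livers were frozen in liquid nitrogen, and total RNA was extracted with Trizol, purified on RNeasy columns and labelled with biotin by the manufacturer's whole transcript method. The deposited values are on a log2 scale, 1 value per probe set and array, and were made with Affymetrix Expression Console per the submitters' processing notes. The version of that program, the summarisation and normalization algorithm and the genome build are not given in the sources used here. Column medians of the deposited values lay between 4.432 and 4.616 and column SDs between 2.075 and 2.333, so the columns did not share 1 distribution, and differences in spread between arrays remained in the values compared. A log2 difference of summarised array signals understates the change of genes near the background, and the number of arrays limits the precision.

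Samples were put in groups by the diet named in their labels. Probe sets were named from the platform annotation: 15310 of 29214 had exactly 1 gene symbol, 323 had several, and 13581 were not listed in it and stay unnamed here. The 15310 probe sets stand for 14506 genes, 527 of them with more than 1 probe set, and 32 probe sets repeated the values of another exactly. The Entrez IDs of 15279 probe sets were found in the RefSeq gene table, where the symbol was the same for all 15279. Probe sets with several symbols or none were left out of the tests, apart from 1 alternative over all probe sets in the file. No genome was used here, so no position is given. Ribosomal protein genes have many near-identical copies in the genome, so which copy a probe set measures is uncertain.

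Differences between diets were tested on the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit on 3 group means over all 12 arrays, then eBayes with default settings), which gave 9 residual and 3.448 prior degrees of freedom. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 15310 probe sets with a threshold of 0.05. Leucine and dairy were each compared with casein, the control, and with each other, and a moderated F test asked whether any diet differed. Gene lists were tested with limma's camera, which sets the genes of a list against all other genes, at a preset correlation between genes of 0.01, with 1 probe set per gene (the highest mean over all arrays) and adjustment over the lists. camera was repeated with a correlation estimated for each list. fry, a rotation test of whether a list's genes moved on balance one way, and an exact two-sided permutation test of per-array list scores were also run. With 4 arrays against 4 the exact test cannot go under 0.0286, and its p-values were not adjusted over the lists.

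The groups, the tests, the alternatives, 35 gene lists, 21 key genes and the rule for naming genes were fixed before the data were examined. The lists covered branched-chain amino acid catabolism, mTORC1 and amino acid sensing, the ATF4 amino acid response, fatty acid and triglyceride synthesis, cholesterol synthesis, fatty acid oxidation with PPAR-alpha targets, gluconeogenesis, glycolysis with fructose and glycogen metabolism, galactose metabolism, insulin signalling, the growth hormone and IGF axis, the urea cycle with amino acid degradation, bile acids, xenobiotic metabolism, NRF2 targets, the circadian clock, acute phase proteins, the interferon response, the unfolded protein response, oxidative phosphorylation, cytosolic ribosomal proteins, autophagy and lysosome, lipoproteins and lipid droplets, and the cell cycle. Further lists held markers of hepatocytes, Kupffer cells and macrophages, lymphocytes, neutrophils, endothelial cells, stellate cells and fibrosis, cholangiocytes, erythroid cells (blood), adipocytes, pancreas and skeletal muscle. All 35 lists had 5 or more measured genes. Some genes belong to more than 1 list.

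Named genes were chosen as follows. Against casein, up to 10 genes each way were taken by largest change among those past the threshold. Free places were filled by the smallest unadjusted p among probe sets whose 4 arrays of 1 diet all lay on one side of the 4 of the other and whose mean was above that of the median probe set. Between the test diets up to 5 each way were taken in the same manner. Up to 4 members of each called list past the threshold, or else the 4 with the largest moderated t in the list's direction, and the key genes were added. A list of inducible inflammatory genes and a list of mitochondrial ribosomal proteins were written after the data were seen.

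The alternatives were quantile normalization of the deposited values, centring of each array on its median, all probe sets in the file, leaving out the dimmest probe sets, eBayes with trend and robust, array quality weights, the replicate number as a block, only the 8 arrays of the 2 diets compared, other thresholds, the mean over all probe sets of a gene, and leaving out each array in turn. Fits without the 2 arrays of narrowest spread, with an acute phase score as a covariate, and with the replicate number as a block over the 8 arrays of leucine and casein were added after seeing the data. The labels do not say what a replicate number shares between diets. Deviations from the diet means of same-number arrays correlated with r from 0.208 to 0.532 in all 4 pairs of leucine and casein, from -0.505 to 0.502 in those of dairy and casein, and from -0.304 to 0.59 in those of leucine and dairy. For leucine and casein, 4 of the 24 ways to match the arrays gave 4 pairs over 0.1, and 3 of 24 had a mean r as high as the same-number pairs. The data thus do not establish that the numbers are pairs, and the block over these 8 arrays serves only as an alternative. The steps were tested on simulated data with the residual SD of each probe set over all arrays, in which 200 of 15310 probe sets were changed in the dairy arrays. The fit recovered 8.96% of probe sets changed 1.5-fold, 56.7% of those changed 2-fold and 93.9% of those changed 4-fold, with 8 false calls. A simulated list of 30 genes shifted by 0.5 among 14506 genes was called by camera (adjusted p = 2.1e-16, and 0.00015 with an estimated correlation), with 0 of the 35 other lists called. Genes were drawn independently of each other here, so the simulation does not show how often lists of correlated genes are called falsely. For the same reason it does not give the recovery or false calls of probe sets among arrays that share a structure besides diet. Other splits of the real dairy and casein arrays called up to 101 probe sets. Scripts used the R package data.table, version 1.17.8, and, for figures, Python 3.11.15 with matplotlib 3.10.9 and pandas 2.3.3.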

Results

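Hepatic gene expression was measured in 12 male rats of a diet-induced obese Sprague-Dawley strain that ate 1 of 3 high fat, high sucrose diets from 12 to 20 weeks of age. Casein, the main protein of milk, was the control. The dairy diet took its protein from skim milk powder, and in the leucine diet casein supplied 7.1% and free leucine 2.9% of the energy. Protein supplied 10% of energy in each diet, the energy density was 4.6 kcal per gram, and each diet was eaten freely for 8 weeks. There were 4 liver samples per diet, numbered 1 to 4 and read here as 1 sample per rat. The p-values of limma and of the exact permutation test weigh differences against the spread between these samples. The camera p-values at the preset correlation set the genes of a list against other genes and treat genes as nearly independent. They do not measure how far a list as a whole varies between rats. The comparisons address how the leucine diet and the dairy diet, each as a whole, differ from casein in liver gene expression. Casein supplied 7.1% of energy in the leucine diet and 10% in the casein diet, so added leucine cannot be told apart from less casein. Dairy protein likewise cannot be told apart from the other parts of skim milk powder.

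Log2 signals ranged from 1.06 to 14.37, and 15310 probe sets with exactly 1 gene symbol were compared. Arrays of the same diet were no closer to each other than arrays of different diets (median r across probe sets of 0.9639 within and 0.9683 between diets). The SD over probe sets was lowest for dairy replicate 3 (2.075) and casein replicate 4 (2.138) and reached 2.333 for casein replicate 1. The first and the second principal component took 38.98% and 23.25% of the variance.

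Livers of dairy-fed rats had higher signals than livers of casein-fed rats for 5 genes of cytosolic ribosomal proteins, the protein part of the ribosome. Rps15a, a protein of the small ribosomal subunit, rose 3.59-fold with dairy, from a log2 signal of 6.59 ± 0.185 to 8.44 ± 0.258 (SD, n = 4 per diet; limma adjusted p = 0.00307). Rps19 rose 2.63-fold (log2 difference 1.40 ± 0.217 SE, adjusted p = 0.0384) and Rpl39 2.37-fold (1.24 ± 0.200 SE, adjusted p = 0.0436). Rps9 rose 2.14-fold (1.10 ± 0.162 SE, adjusted p = 0.027) and Rpl41 2.11-fold (1.08 ± 0.146 SE, adjusted p = 0.0149). These 5 genes, all of them ribosomal proteins, accounted for the 13 probe sets that limma called, and all 13 were higher with dairy. All 6 probe sets of Rps15a passed, with changes of 2.62-fold to 3.59-fold. So did 2 of 5 probe sets of Rps19, 2 of 7 of Rpl39, 2 of 3 of Rpl41 and 1 of 3 of Rps9. The leading probe sets were 10760208 for Rps15a, 10795546 for Rps19, 10803301 for Rpl39, 10718510 for Rps9 and 10899824 for Rpl41. Of the genes nearest to the threshold, Rps12 (1.33), Rpl23a (0.993), Rpl32 (0.771), Chchd2l3 (1.17) and the splicing factor subunit Sf3b5 (1.06) had higher log2 signals with dairy, with adjusted p from 0.0531 to 0.0535.

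The list of cytosolic ribosomal proteins, which was fixed with Rps9 and Rps19 but without Rps15a, Rpl39 and Rpl41, rose as a group with dairy, by a mean log2 difference of 0.301 over 49 measured genes (camera adjusted p = 4.87e-10). With an estimated correlation the adjusted p = 0.416, and the exact permutation test of the list score gave p = 0.0857 with n = 4 per diet. Of its genes 36 had higher and 13 lower signals, 17 were higher at an unadjusted p under 0.05, 1 (Rps9) passed over all probe sets, and 16 passed when adjusted over the list alone. Erythroid markers, which come with blood in the tissue, were also higher with dairy, by 0.352 over 7 genes (camera adjusted p = 0.0713). Their exact permutation p, not adjusted over the lists, was 0.0286 with n = 4 per diet, the smallest possible.

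Genes for the urea cycle and amino acid degradation, which turn surplus amino acid nitrogen into urea, fell as a group with dairy, by a mean of 0.71 on the log2 scale. All 33 measured genes had lower signals than with casein (camera adjusted p = 4.79e-15). With an estimated correlation the adjusted p = 0.416. The exact permutation p, not adjusted over the lists, was 0.0286 with n = 4 per diet, the smallest possible. No gene of the list passed over all probe sets, 22 had an unadjusted p under 0.05, and 17 passed when adjusted over the list alone. Bhmt, which remethylates homocysteine with betaine, had a log2 signal of 11.76 ± 0.210 with dairy and 12.89 ± 0.338 with casein (SD, n = 4; limma adjusted p = 0.0633). Casein replicate 1 alone stood at 13.4. Prodh, the first enzyme of proline breakdown, differed by -1.36 ± 0.291 (SE, adjusted p = 0.112). The ornithine aminotransferase Oat differed by -1.24 ± 0.271 (SE, adjusted p = 0.124) and the glycine methyltransferase Gnmt by -1.0 ± 0.206 (SE, adjusted p = 0.102). Hepatocyte identity markers, such as albumin, differed by -0.0567 over 13 genes (camera adjusted p = 0.465).

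Branched-chain amino acid catabolism, the route that breaks down leucine, isoleucine and valine, fell as a group with dairy, by a mean of 0.42, with 21 of 23 genes lower (camera adjusted p = 1.32e-05). The adjusted p = 0.731 with an estimated correlation, 11 genes were lower at an unadjusted p under 0.05, and 0 passed limma's test over all probe sets or when adjusted over the list alone. Ivd and Mccc2, both in the leucine branch, differed by -0.542 ± 0.163 and -0.651 ± 0.209 (SE). Aldh6a1 and Pcca, in the valine and propionate branch, differed by -0.588 ± 0.216 and -0.516 ± 0.198 (SE; adjusted p from 0.296 to 0.385). Bcat2 and the kinase Bckdk, which inhibits the rate-limiting dehydrogenase of the pathway, differed by 0.26 ± 0.122 and -0.128 ± 0.319 (SE).

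**Figure D1:**
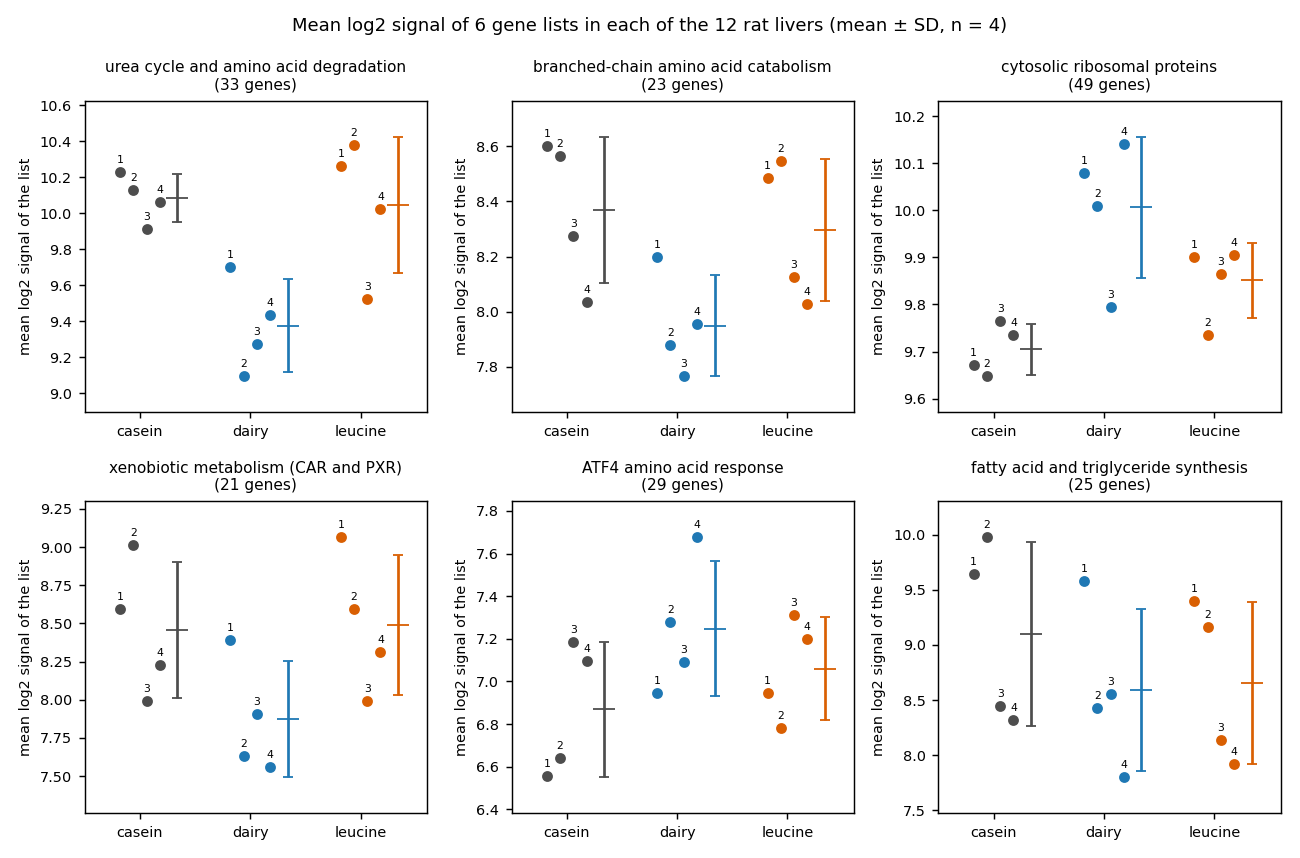
Mean log2 signal of 6 gene lists (vertical axes) in each of the 12 livers, by diet; points are single rats with their replicate number, and the bar gives the mean ± SD of 4 rats. The 4 dairy values of the urea cycle and amino acid degradation list lie between 9.09 and 9.70, under the casein values of 9.91 to 10.23, while values of fatty acid and triglyceride synthesis spread widely within each diet.

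The list of xenobiotic metabolism genes was drawn up around the nuclear receptors CAR and PXR and is not confined to their targets. It fell as a group with dairy, by a mean of 0.583, with 20 of 21 genes lower (camera adjusted p = 9.53e-04). The adjusted p = 0.731 with an estimated correlation, 3 genes were lower at an unadjusted p under 0.05 and 1 passed when adjusted over the list alone. The glucuronosyltransferase Ugt2b1 had signals of 6.97 ± 0.938 with dairy and 8.90 ± 0.858 with casein (SD, n = 4; limma adjusted p = 0.176). Dairy replicate 1, at 8.37, stood apart from the other 3 dairy rats. The cytochromes P450 Cyp3a9, Cyp2e1 and Cyp3a23-3a1 differed by -1.59 ± 0.476, -0.752 ± 0.266 and -0.755 ± 0.353 (SE). Targets of ATF4, the transcription factor that answers amino acid shortage and other stresses, rose as a group by 0.379, with 21 of 29 genes higher (camera adjusted p = 2.38e-03). The adjusted p = 0.494 with an estimated correlation. In this list 5 genes were higher at an unadjusted p under 0.05 and 2 passed when adjusted over the list alone. The serine synthesis enzymes Phgdh and Psat1 differed by 1.43 ± 0.356 and 1.22 ± 0.397 (SE), and a second probe set of Psat1 by 0.193. Trib3 and Ddit4, which restrain growth signalling, differed by 1.16 ± 0.306 and 1.17 ± 0.350 (SE; adjusted p from 0.204 to 0.32). Without dairy replicate 4 the mean difference of the ATF4 list was 0.236 and its call ended (adjusted p = 0.0842).

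The other 5 lists called with dairy each had a camera adjusted p = 0.0409, and an adjusted p = 0.832 with an estimated correlation. Each had 0 genes past limma's threshold, over all probe sets or adjusted over the list alone. Fatty acid and triglyceride synthesis fell by 0.507 (23 of 25 genes lower, 0 at an unadjusted p under 0.05). In this list Elovl5 stood at -0.791 ± 0.415, Acss2 at -0.771 ± 0.463, Agpat2 at -0.554 ± 0.342 and Nr1h3 at -0.416 ± 0.235 (SE). Its call ended without casein replicate 1, casein replicate 2, dairy replicate 2, dairy replicate 3 or dairy replicate 4 (adjusted p = 0.261, 0.576, 0.137, 0.0529 and 0.609). Its mean ran from -0.838 without dairy replicate 1 to -0.213 without casein replicate 2. Fatty acid oxidation and PPAR-alpha targets fell by 0.223 (28 of 35 lower, 3 at an unadjusted p under 0.05). Its members included the peroxisomal enzyme Ehhadh at -1.06 ± 0.284, Cd36 at -0.969 ± 0.426, Acadm at -0.672 ± 0.285 and Etfa at -0.592 ± 0.282 (SE). Bile acid synthesis and transport fell by 0.349 (19 of 20 lower, 2 at an unadjusted p under 0.05). Its members included Cyp27a1 at -0.605 ± 0.213, Amacr at -0.549 ± 0.244, the bile acid importer Slc10a1 at -0.547 ± 0.313 and Slc27a5 at -0.361 ± 0.224 (SE). The calls of both lists ended without casein replicate 1 (adjusted p = 0.205 and 0.161), casein replicate 2 (0.472 and 0.135), dairy replicate 2 (0.349 and 0.137) or dairy replicate 4 (0.407 for each). Without dairy replicate 1 their means were -0.382 and -0.524. Without casein replicate 1, casein replicate 2, dairy replicate 2 and dairy replicate 4 that of fatty acid oxidation was -0.137, -0.118, -0.133 and -0.143, and without dairy replicate 4 that of bile acids was -0.23.

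Neutrophil markers rose with dairy by 0.488 (10 of 12 higher, 1 at an unadjusted p under 0.05). In this list Ncf1 stood at 1.02 ± 0.404, S100a9 at 1.40 ± 1.13, Mmp9 at 0.657 ± 0.495 and Fpr1 at 0.368 ± 0.297 (SE). Stellate cell and fibrosis markers rose by 0.221 (15 of 21 higher, 3 at an unadjusted p under 0.05). Its members included Des at 0.703 ± 0.312, Col4a1 at 0.591 ± 0.263, Loxl2 at 0.383 ± 0.156 and Pdgfrb at 0.34 ± 0.175 (SE). Both lists had an adjusted p = 0.832 with an estimated correlation. The neutrophil call ended without casein replicate 1, casein replicate 2, casein replicate 4, dairy replicate 2 or dairy replicate 4 (adjusted p = 0.205, 0.149, 0.0968, 0.137 and 0.407). The mean ran from 0.177 without dairy replicate 4 to 0.855 without casein replicate 3. The stellate call ended without casein replicate 1, casein replicate 2, casein replicate 4, dairy replicate 1 or dairy replicate 2 (adjusted p = 0.214, 0.135, 0.1, 0.174 and 0.105). The mean ran from 0.107 without casein replicate 1 to 0.386 without casein replicate 3.

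The remaining lists were not called between dairy and casein. Galactose metabolism, the route of the sugar of milk, differed by -0.373 (5 of 6 genes lower, 1 adjusted over the list alone, camera adjusted p = 0.0879). Gluconeogenesis differed by -0.361, with 1 gene higher and 2 lower adjusted over the list alone, and glycolysis, fructose and glycogen metabolism by -0.306. NRF2 targets differed by -0.211, autophagy and lysosome genes by -0.195, cholesterol synthesis by -0.194, lipoprotein and lipid droplet genes by -0.122, and the circadian clock by -0.0918. Oxidative phosphorylation differed by -0.0838, with 2 genes higher adjusted over the list alone, mTORC1 and amino acid sensing by -0.0652 and the growth hormone and IGF axis by -0.0611. Insulin signalling was Down by camera with a mean of 0.0248 and a median of -0.0463. Acute phase proteins differed by 0.339, the interferon response by 0.217, the unfolded protein response by 0.138 and the cell cycle by 0.0941. Of the other marker lists, Kupffer cells and macrophages differed by 0.18, pancreas by 0.116, adipocytes by 0.102, skeletal muscle by 0.0995, lymphocytes by 0.0708, cholangiocytes by -0.0745 and endothelial cells by -0.129. Adjusted p of these uncalled lists lay between 0.067 and 0.748.

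Outside the lists, the genes lower with dairy that lay nearest to the threshold were the lysosomal protease Ctsk (-0.906), the mitochondrial ribosome assembly factor Mtg1 (-0.874), and the pseudouridine synthase Trub1 (-0.873). Ntaq1 (-0.817), Lzic (-0.804) and Dtd2 (-1.0) followed, and adjusted p ran from 0.0583 to 0.124. Of the 21 key genes 16 had a probe set, and the other 5 were not analysed here. None of the 16 passed limma's threshold with dairy, 4 had an unadjusted p under 0.05, and 3 passed when adjusted over the list alone. Those 3 were Trib3, the coactivator Ppargc1a (-1.10 ± 0.329 SE, adjusted p = 0.295 over all probe sets) and the insulin receptor Insr (-0.644 ± 0.195 SE, adjusted p = 0.301), whose other probe set differed by -0.116. Asparagine synthetase Asns differed by 1.20 ± 0.482 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by -1.69 ± 1.15 (SE). The lipogenic enzymes Acaca, Fasn and Scd differed by -0.491 ± 0.425, -0.571 ± 0.832 and -0.322 ± 0.997 (SE), and Cpt1a, which admits fatty acids to mitochondria, by -0.528 ± 0.407. The gluconeogenic enzymes Pck1 and G6pc1 differed by -0.14 ± 0.468 and -0.852 ± 1.44, and Pdk4, Igfbp1 and the hormone Fgf21 by -0.694 ± 0.732, 0.504 ± 0.957 and 0.398 ± 0.777 (SE). With single arrays left out, Acaca ran from -0.879 (without casein replicate 4) to -0.232 (without casein replicate 1), Fasn from -1.14 (without dairy replicate 1) to -0.0503 (without casein replicate 2) and G6pc1 from -1.78 (without casein replicate 3) to -0.219 (without casein replicate 2). Pdk4 ran from -1.18 (without dairy replicate 1) to -0.104 (without dairy replicate 4), Cpt1a reached -0.267 (without dairy replicate 2), Cyp7a1 -2.65 (without casein replicate 3) and Bckdk -0.00394 (without casein replicate 1). The sign turned for Scd without casein replicate 2 (0.38) or dairy replicate 4 (0.277), and for Pck1 without casein replicate 2 (0.0833) or dairy replicate 2 (0.0452). It also turned for Igfbp1 without casein replicate 1 (-0.115) or dairy replicate 4 (-0.189), and for Fgf21 without casein replicate 3 (-0.222) or dairy replicate 3 (-0.266).

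**Figure D2:**
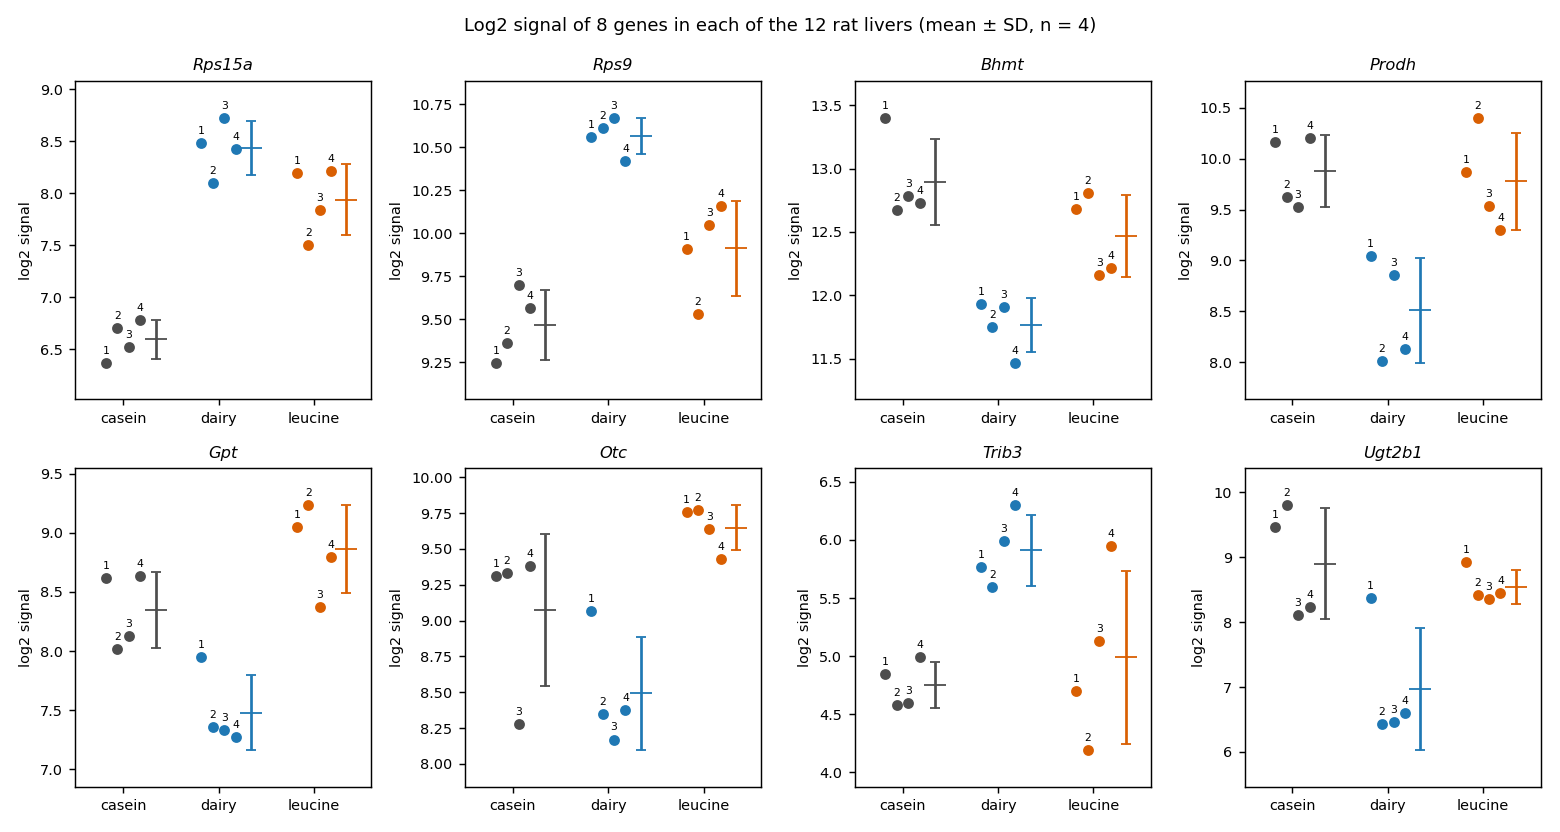
Log2 signal (vertical axes) of 8 genes in each of the 12 livers, by diet; points are single rats with their replicate number, and the bar gives the mean ± SD of 4 rats. Rps15a lies between 8.10 and 8.73 with dairy and between 6.37 and 6.78 with casein, and single rats stand apart from the rest of their diet for Otc (casein replicate 3, 8.28), Gpt (dairy replicate 1, 7.95) and Ugt2b1 (dairy replicate 1, 8.37).

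Between dairy and casein 1670 probe sets had an unadjusted p under 0.05 (702 higher and 968 lower), where 766 are due by chance. This count was 935 without casein replicate 1, 3244 without casein replicate 4, 2664 without both arrays of narrowest spread and 4484 with array quality weights. In 654 (4.27%, against 2.86% by chance) the 4 values of 1 diet all lay above those of the other. Rps15a kept its call when each array was left out in turn, while Rpl41 lost it without casein replicate 1 or dairy replicate 1 (highest adjusted p 0.0724). Rps9 kept it only without casein replicate 3, casein replicate 4, leucine replicate 2 or leucine replicate 4, Rps19 only without casein replicate 3 or casein replicate 4, and Rpl39 only without casein replicate 4 or dairy replicate 3. Their highest adjusted p was 0.13, 0.151 and 0.2. With only the 8 arrays of these diets the calls of Rpl41, Rps9, Rps19 and Rpl39 ended (adjusted p = 0.188, 0.104, 0.207 and 0.214), and with trend and robust those of Rps9, Rps19 and Rpl39 (0.0512, 0.0529 and 0.0703). The acute phase covariate ended those of Rps19 and Rpl39 (limma adjusted p = 0.0503 for each), and the replicate block that of Rpl39 (0.0719). The count of 13 probe sets became 3 without casein replicate 1, 6 without casein replicate 2, 237 (161 higher and 76 lower) without casein replicate 4. It was 3 without dairy replicate 1, 7 without dairy replicate 2, 8 without dairy replicate 4, 7 without leucine replicate 1 and 8 without leucine replicate 3. Without both arrays of narrowest spread, a choice made after seeing the data, it was 164, with 130 higher and 34 lower. With array quality weights it was 1182, with 523 higher and 659 lower, after quantile normalization 39, with 34 higher and 5 lower, and over all probe sets in the file 42, with 37 higher and 5 lower. It was 8 with trend and robust and 6 with only the 8 arrays of these diets. The 10 called lists became 5 without casein replicate 1, casein replicate 2, dairy replicate 2 or dairy replicate 4, and 18 without dairy replicate 1. The urea cycle, ribosomal, branched-chain and xenobiotic lists were called each time. After quantile normalization the calls of fatty acid and triglyceride synthesis, fatty acid oxidation, bile acids and neutrophil markers ended (adjusted p = 0.152, 0.188, 0.0878 and 0.139). Without the dimmest probe sets those of the first 3 ended (0.102, 0.102 and 0.0864), and with trend and robust that of stellate cell markers (0.0521). With the acute phase score as a covariate, a fit added after seeing the data, 5 lists were called. The calls of fatty acid and triglyceride synthesis, fatty acid oxidation, bile acids, neutrophil markers and stellate cell markers then ended.

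Between leucine and casein the list of cytosolic ribosomal proteins was called higher with leucine, by a mean of 0.147, with 32 of 49 genes higher and 17 lower (camera adjusted p = 1.02e-05, and adjusted p = 0.995 with an estimated correlation). The exact permutation p was 0.0857 with n = 4 per diet. Of them 9 were higher at an unadjusted p under 0.05, and 0 passed limma's test over all probe sets or adjusted over the list alone. Rps15a, which is outside the list, had a log2 signal of 7.94 ± 0.34 with leucine and 6.59 ± 0.185 with casein, a 2.54-fold difference (SD, n = 4; limma adjusted p = 0.12). Of the members, Rps29 differed by 0.70 ± 0.228, Rplp2 by 0.464 ± 0.166, Rps9 by 0.447 ± 0.162 and Rpl22 by 0.327 ± 0.132 (SE; adjusted p = 0.999 each).

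Erythroid markers rose with leucine by a mean of 0.561, with 7 of 7 genes higher (camera adjusted p = 4.17e-04, and adjusted p = 0.995 with an estimated correlation). Of them 2, Hbb-b1 (1.24 ± 0.389 SE) and Hbb (1.10 ± 0.427 SE), both beta globins, had an unadjusted p under 0.05, and 0 passed limma's test over all probe sets or adjusted over the list alone. Alas2 and Slc4a1 differed by 0.695 ± 0.506 and 0.406 ± 0.341 (SE), and Slc4a1 by -0.0136 without leucine replicate 3. Leucine replicate 3 had the highest list mean (7.06), and without it the difference was 0.235 and the call ended (adjusted p = 0.168). Fatty acid and triglyceride synthesis fell with leucine by a mean of 0.441, with 23 of 25 genes lower and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.03, and adjusted p = 0.995 with an estimated correlation). Fatty acid synthase Fasn differed by -1.04 ± 0.832, Me1 by -0.943 ± 0.761, Acacb by -0.695 ± 0.593 and Nr1h3 by -0.321 ± 0.235 (SE), with 0 genes past the threshold adjusted over the list alone. The call ended without casein replicate 1, casein replicate 2, dairy replicate 3, leucine replicate 3 or leucine replicate 4 (adjusted p = 0.597, 0.871, 0.0646, 0.26 and 0.601). The mean ran from -0.7 without casein replicate 4 to -0.147 without casein replicate 2.

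Branched-chain amino acid catabolism, which degrades leucine itself, differed by -0.0737 with leucine (14 of 23 genes lower, camera adjusted p = 0.937), mTORC1 and amino acid sensing by -0.0492 (0.934) and ATF4 targets by 0.191 (0.0718). The urea cycle list differed by -0.0397, xenobiotic metabolism by 0.0339 and fatty acid oxidation by -0.0754. Neutrophil markers differed by 0.371, the interferon response by -0.415 (camera adjusted p = 0.0511), acute phase proteins by 0.228 and hepatocyte identity markers by -0.0971. Camera's direction was opposite to the mean for gluconeogenesis (Up, -0.0811), the circadian clock (Up, -0.0311), the unfolded protein response (Up, -0.0578), oxidative phosphorylation (Up, -0.0337), autophagy and lysosome (Up, -0.0403), the cell cycle (Up, -0.0242) and cholangiocytes (Up, -0.033). The medians of these 7 lists were also below 0. For bile acids (Up, mean 0.0247, median -0.0594) and lymphocytes (Down, mean -0.0224, median 0.0215) camera went with the mean and against the median.

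No probe set passed limma's adjusted threshold between leucine and casein, where the lowest adjusted p was 0.12. There were 507 probe sets with an unadjusted p under 0.05 (213 higher and 294 lower), where 766 are due by chance, and 373 (2.44%, against 2.86% by chance) had separate diets. The unadjusted count was 894 with the replicate number as a block over the 8 arrays of leucine and casein, 1974 with array quality weights, 1826 without both arrays of narrowest spread and 1358 without casein replicate 4, so it lies on either side of chance. Higher signals nearest to the threshold were those of Prdx6, a peroxiredoxin (0.828), Rpl39 (0.784), Chchd2l3 (0.757), Cox7a2l (0.659), Rpl17 (0.613), Arpc1a (0.58), Rpl23a (0.571), Rpl31 (0.565) and Rbis (0.476). The 7 probe sets of Rpl31 ran from -0.431 to 0.575. Lower signals were those of Acsm5, a mitochondrial acyl-CoA synthetase (-2.0), Sirt7 (-0.776), Lzic (-0.754), Tceal8 (-0.722), Rhog (-0.706), Icmt (-0.621), Use1 (-0.545), Fis1 (-0.536), Trim65 (-0.50) and Asb8 (-0.488), all with adjusted p = 0.999. Of the 16 key genes 0 passed limma's test, with or without adjustment, or adjusted over the list alone. Igfbp1, a binding protein of insulin-like growth factors, had the lowest p of them, with a signal of 11.84 ± 0.598 with leucine and 9.99 ± 1.96 with casein (SD, n = 4; limma adjusted p = 0.999). G6pc1 differed by -1.84 ± 1.44, Cyp7a1 by -0.688 ± 1.15, Pdk4 by -0.645 ± 0.732, Scd by -0.584 ± 0.997, Acaca by -0.47 ± 0.425 and Fgf21 by -0.434 ± 0.777 (SE). Bckdk differed by -0.347 ± 0.319, Ppargc1a by -0.338 ± 0.329, Insr by -0.244 ± 0.195, Trib3 by 0.239 ± 0.306, Asns by 0.183 ± 0.482, Cpt1a by -0.18 ± 0.407, Pck1 by -0.163 ± 0.468 and Bcat2 by 0.0344 ± 0.122 (SE). With single arrays left out, Fasn reached -0.521 (without casein replicate 2), Acaca -0.211 (without casein replicate 1), G6pc1 -0.76 (without leucine replicate 3), Pdk4 -0.192 (without leucine replicate 3) and Fgf21 -0.077 (without casein replicate 4). Without leucine replicate 3 the sign turned for Cyp7a1 (0.275), Scd (0.175), Cpt1a (0.104), Pck1 (0.32) and Bcat2 (-0.00918). It turned without casein replicate 2 for Scd (0.118), Cpt1a (0.073), Pck1 (0.0603) and Asns (-0.19), without casein replicate 3 for Ppargc1a (0.0102), and without leucine replicate 4 for Asns (-0.108) and Trib3 (-0.0805). Without leucine replicate 2, 2 probe sets passed, with adjusted p = 0.0429 for Rps15a. With the replicate number as a block over the 8 arrays of leucine and casein, a fit added after seeing the data, Acsm5 alone passed (-2.0, limma adjusted p = 0.0362), and casein replicate 3, at 7.69, stands apart from the other casein rats in this gene. Neutrophil markers, the interferon response and ATF4 targets were then called as well (camera adjusted p = 1.37e-05, 1.62e-04 and 0.0175), and with an estimated correlation their adjusted p = 0.241, 0.993 and 0.407. The 3 called lists became 7 without casein replicate 3, 5 without casein replicate 4, 8 without leucine replicate 1, 5 without leucine replicate 2 and 7 without leucine replicate 3.

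Leucine was also set directly against dairy. The urea cycle and amino acid degradation list was called higher with leucine, by a mean of 0.67, with 31 of 33 genes higher (camera adjusted p = 1.09e-17, and adjusted p = 0.572 with an estimated correlation). The exact permutation p was 0.0571 with n = 4 per diet, 19 genes were higher at an unadjusted p under 0.05, and 17 passed when adjusted over the list alone. The alanine aminotransferase Gpt had a log2 signal of 8.86 ± 0.372 with leucine and 7.48 ± 0.317 with dairy (SD, n = 4). Otc, the ornithine transcarbamylase of the urea cycle, had 9.65 ± 0.156 and 8.49 ± 0.395 (SD, n = 4; limma adjusted p = 0.604 for each). Prodh and Oat differed by 1.26 ± 0.291 and 1.21 ± 0.271 (SE). Branched-chain amino acid catabolism was called higher with leucine, by 0.346 (18 of 23 genes higher, 5 adjusted over the list alone, camera adjusted p = 6.27e-06, and adjusted p = 0.77 with an estimated correlation). In it Acadsb differed by 0.931 ± 0.276, Dbt by 0.802 ± 0.236, Mccc2 by 0.726 ± 0.209 and Pcca by 0.72 ± 0.198 (SE).

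Xenobiotic metabolism was called higher with leucine than with dairy, by 0.617, with 21 of 21 genes higher and 5 past the threshold adjusted over the list alone (camera adjusted p = 9.05e-07, and adjusted p = 0.72 with an estimated correlation). Cyp3a9 differed by 1.64 ± 0.476, Ugt2b1 by 1.57 ± 0.462, Cyp3a23-3a1 by 1.15 ± 0.353 and Cyp2e1 by 0.921 ± 0.266 (SE). Bile acid synthesis and transport was called higher, by 0.373 (18 of 20 genes, camera adjusted p = 3.16e-03, and adjusted p = 0.77 with an estimated correlation). It included the uptake transporter Slco1b2 at 0.86 ± 0.308, Abcg5 at 0.814 ± 0.368, Abcb4 at 0.564 ± 0.284 and Cyp27a1 at 0.463 ± 0.213 (SE). Its mean was 0.236 without leucine replicate 1, and its call ended without dairy replicate 4 (0.255, adjusted p = 0.237). Fatty acid oxidation and PPAR-alpha targets were called higher by 0.148 (24 of 35 genes, camera adjusted p = 0.0385, and adjusted p = 0.869 with an estimated correlation). Their call ended without dairy replicate 2 (0.0576), dairy replicate 4 (0.0677) or leucine replicate 1 (0.0158, adjusted p = 0.512), and the mean was 0.307 without dairy replicate 1. It also ended after quantile normalization, with median centring, without the dimmest probe sets and with the acute phase score as a covariate. In this list Ehhadh differed by 0.674 ± 0.284, Acadm by 0.607 ± 0.285, Decr1 by 0.536 ± 0.255 and Etfa by 0.483 ± 0.282 (SE).

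Called lower with leucine than with dairy was the interferon response, by a mean of -0.632 (23 of 25 genes lower, camera adjusted p = 3.68e-03, and adjusted p = 0.869 with an estimated correlation). Cytosolic ribosomal proteins were also called lower, by -0.155 (36 of 49 lower, 2 adjusted over the list alone, camera adjusted p = 3.83e-04, and adjusted p = 0.77 with an estimated correlation). Of the interferon genes, which answer viral RNA and interferon, Ifit1 differed by -1.74 ± 1.16 (-0.239 without dairy replicate 2), Irf7 by -1.41 ± 0.727, Psmb9 by -1.11 ± 0.517 and Oas1a by -0.835 ± 0.548 (SE). The interferon call ended without dairy replicate 2 (-0.0757, adjusted p = 0.67), dairy replicate 4 (-0.442, adjusted p = 0.19) or leucine replicate 1 (-0.404, adjusted p = 0.102). The mean was -1.05 without dairy replicate 1. Of the ribosomal genes Rps12 differed by -0.882 ± 0.221, Rps19 by -0.726 ± 0.262, Rps9 by -0.653 ± 0.162 and Rps18 by -0.55 ± 0.152 (SE). The call ended without dairy replicate 4 (-0.111, adjusted p = 0.0908). Outside these lists, Pck2, the mitochondrial form of phosphoenolpyruvate carboxykinase, differed by -1.25 ± 0.221 and the interferon-inducible Ifi27l2b by -1.80 ± 0.400 (SE). Chpf2 differed by -0.699 ± 0.152, Rpl41 by -0.684 ± 0.146 and Trim65 by -0.591 ± 0.132 (SE). Higher with leucine were Alcam (1.01 ± 0.218), Wasl (0.837 ± 0.182) and Acsl4, a ligase that activates arachidonic acid (0.718 ± 0.149 SE).

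Among lists not called between the test diets, ATF4 targets differed by -0.188 (camera adjusted p = 0.145), gluconeogenesis by 0.28 (0.126, with 3 genes higher and 1 lower adjusted over the list alone), erythroid markers by 0.209 (0.507), neutrophil markers by -0.117 (0.507) and fatty acid and triglyceride synthesis by 0.0663 (0.725). Directions differed for mTORC1 and amino acid sensing (Down, mean 0.016, median -0.0226), hepatocyte markers (Down, mean -0.0404, median 0.000775) and Kupffer cell and macrophage markers (Down, mean -0.0518, median 0.0249). No probe set passed limma's adjusted threshold, and the lowest adjusted p was 0.604. There were 1064 probe sets with an unadjusted p under 0.05 (559 higher and 505 lower with leucine), where 766 are due by chance, and in 779 (5.09%, against 2.86% by chance) the diets were separate. The unadjusted count was 695 without leucine replicate 2 and 721 without leucine replicate 1, both under that due by chance, and 2147 with array quality weights. Of the 16 key genes 0 passed limma's test over all probe sets or adjusted over the list alone, and 2, Trib3 (-0.921 ± 0.306 SE) and Ppargc1a (0.764 ± 0.329 SE), had an unadjusted p under 0.05. The 7 called lists became 3 without dairy replicate 4, 14 without dairy replicate 1, 12 without dairy replicate 3, 11 without leucine replicate 3 and 13 without leucine replicate 4.

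**Figure D3:**
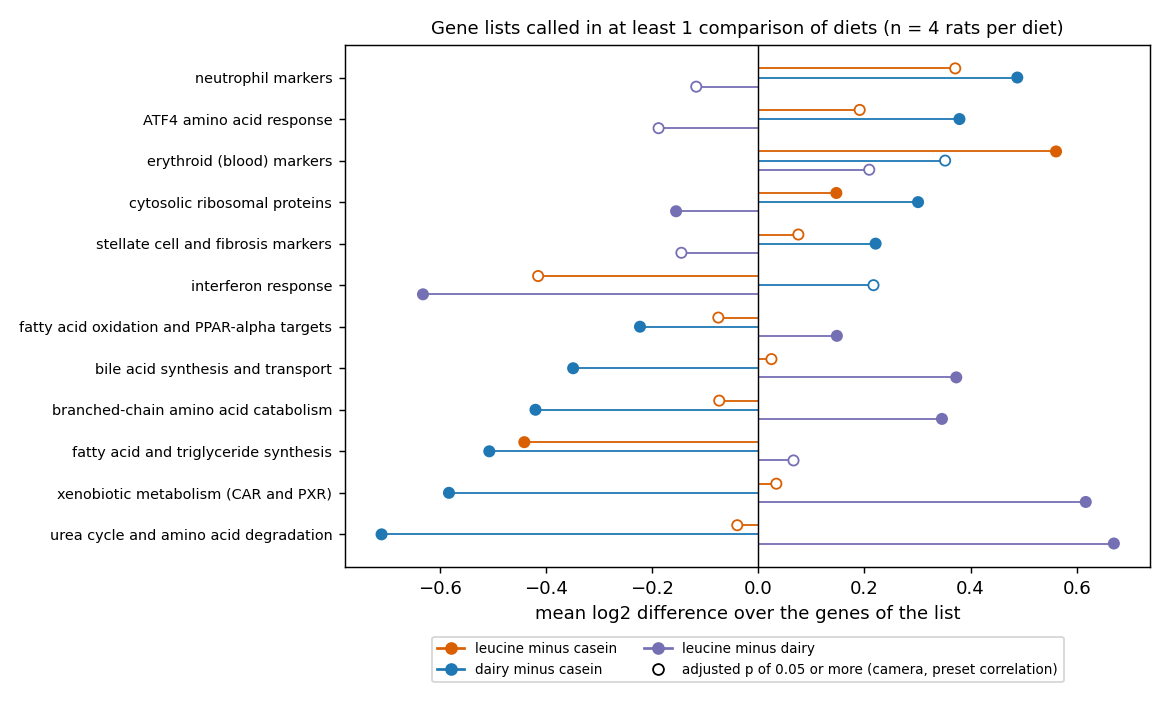
Mean log2 difference (horizontal axis) of the 12 gene lists called by camera in at least 1 comparison, for leucine minus casein, dairy minus casein and leucine minus dairy; open circles mark an adjusted p of 0.05 or more at the preset correlation. The dairy minus casein means run from -0.71 for the urea cycle and amino acid degradation to 0.488 for neutrophil markers, and with an estimated correlation 0 of the lists are called.

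Over the 3 diets together, limma's F test called 5 probe sets, all of Rps15a, and 1188 had an unadjusted p under 0.05 (785 without casein replicate 1, 2433 without casein replicate 4, 2146 without both arrays of narrowest spread and 3739 with array quality weights). The count of calls was 0 without casein replicate 1, casein replicate 2 or casein replicate 3, and 23 without casein replicate 4. It was 2 without dairy replicate 1, dairy replicate 3 or dairy replicate 4, and 3 without leucine replicate 1 or leucine replicate 3. Across 14506 genes, which are not independent replicates, the differences of leucine and of dairy from casein correlated with r = 0.485. Both share the casein arrays, and 100 simulated pairs of unchanged groups that shared them gave a median r of 0.515 (95% range -0.335 to 0.894). The observed covariance of 0.0383 lay 0.0123 under the simulated mean of 0.0506. With the casein arrays split 2 and 2 the mean r was -0.0791 over 6 ways (range -0.353 to 0.0927), and r was 0.316 without leucine replicate 3. Across the 3 comparisons no list call held with an estimated correlation. fry called 0 lists after adjustment, with 0, 4 and 2 at an unadjusted p under 0.05 for leucine against casein, dairy against casein and leucine against dairy.

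The spread between rats of 1 diet was large for immune genes, as the plot of 3 gene lists by rat shows. The mean of the interferon list ran from 5.75 to 8.74 over the 12 rats, with an SD of 1.37 within the dairy diet, and its within-diet SD (1.05) was the highest of the 35 lists. Acute phase proteins ranged from 10.56 in casein replicate 2 to 12.25 in dairy replicate 4.

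**Figure D4:**
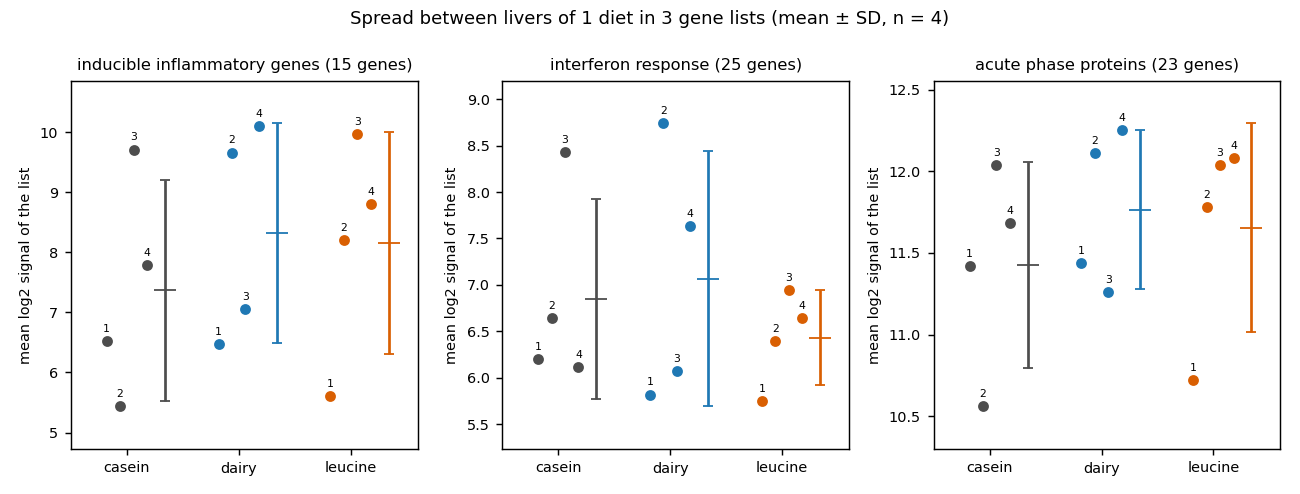
Mean log2 signal (vertical axes) of inducible inflammatory genes (a list chosen post hoc), the interferon response and acute phase proteins in each of the 12 livers, by diet; points are single rats with their replicate number, and the bar gives the mean ± SD of 4 rats. The inflammatory means run from 5.44 to 10.1, with an SD of 1.84 for casein, 1.83 for dairy and 1.85 for leucine.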

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

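The tests of regrouped arrays were set before the data were examined, while the tests of array spread, acute phase state, matched random lists, hepatocyte share and replicate number were chosen after the result was seen.

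Within each diet, the value of 1 array far from the other 3 was sought with Dixon's ratio (critical ratio 0.829) for named genes, gene lists and array measures. It marked 25 of 456 groups of 4 (5.48%), where chance marks about 1 in 20, and the marked values were 22 of genes, 2 of lists and 1 of an array measure. Dairy replicate 1 held 6 of them, leucine replicate 3 held 4, casein replicate 3, dairy replicate 3 and leucine replicate 1 held 3 each, casein replicate 1 and casein replicate 4 held 2 each, and dairy replicate 4 and leucine replicate 2 held 1 each.

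In casein replicate 3, Acsm5 stood at 7.692 (other 3 rats 8.716 to 8.763), Fis1 at 8.929 (9.104 to 9.127) and Otc at 8.279 (9.311 to 9.377). In casein replicate 4, Rplp2 stood at 10.52 (9.924 to 10.01) and Pcca at 7.29 (7.785 to 7.819). In casein replicate 1, Rpl22 stood at 8.297 (8.389 to 8.403) and Bhmt at 13.4 (12.67 to 12.78). The low value of Acsm5 in casein replicate 3 lies toward the leucine rats, and the low value of Otc there toward the dairy rats.

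In dairy replicate 1, Ugt2b1 stood at 8.368 (other 3 rats 6.43 to 6.596), Trim65 at 6.888 (6.441 to 6.511), Ctsk at 4.704 (4.938 to 4.974), Ivd at 9.015 (8.703 to 8.743), Gpt at 7.952 (7.276 to 7.359) and the lipoprotein and lipid droplet list at 9.63 (9.253 to 9.287). In dairy replicate 3 the SD over all probe sets was 2.075 (2.268 to 2.284), the skeletal muscle markers had a mean of 4.152 (3.869 to 3.896) and Rplp2 stood at 10.35 (10.71 to 10.78). In dairy replicate 4, Bcat2 stood at 5.305 (5.004 to 5.041).

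In leucine replicate 1, Cox7a2l stood at 9.345 (other 3 rats 9.008 to 9.012), Ugt2b1 at 8.931 (8.362 to 8.448) and Cyp3a23-3a1 at 11.01 (9.962 to 10.09). In leucine replicate 2, Lzic stood at 5.808 (5.376 to 5.446). In leucine replicate 3, Slc4a1 stood at 6.003 (4.235 to 4.436), Sf3b5 at 7.179 (6.67 to 6.755), Oas1a at 3.748 (4.99 to 5.09) and Ifit1 at 4.967 (3.436 to 3.596). No array was left out of the tests of the report for these values.

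Of the 13904 probe sets without exactly 1 symbol, 22 passed the adjusted threshold between dairy and casein when all probe sets were tested (17 higher and 5 lower), and 0 did in the other comparisons. They were not named or analysed further here.

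For the probe sets called between dairy and casein, 2 of 35 splits of the same 8 arrays gave as many as the 13 of the real split, and the highest other split gave 101, so chance is not excluded. The 10 lists of that comparison were reached in 14 of 35 splits, with 24 in the highest other. The 3 lists between leucine and casein were reached in 32 of 35 splits (20 in the highest other), and the 7 lists between leucine and dairy in 30 of 35 (24 in the highest other). Of the 8 splits of leucine and casein that part all 4 same-number pairs, 5 reached 3 lists (11 in the highest other), while splits that part fewer pairs gave up to 20. Over the 3 diets the 5 probe sets were reached in 9 of 100 regroupings, with 167 in the highest other. Chance is not excluded for any of these counts. For the 0 probe sets of leucine against casein and of leucine against dairy the splits decide nothing, as each of the 35 splits has at least 0, and the highest others gave 357 and 343. The large counts of some splits point to a structure of the samples that the diets do not describe. The first principal component had negative loadings only in casein replicate 3, dairy replicates 2 and 4 and leucine replicates 3 and 4. Those rats also had the highest means of the post hoc inflammatory list, which is no independent support, as that list was chosen after the data were seen. In each pair of diets, the split with the most probe sets put those present on 1 side, beside casein replicate 4 where casein was included. The cause of this grouping was not tested.

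Cytosolic ribosomal proteins were higher with dairy than with casein by 0.301 ± 0.0729 (SE). Without the 2 arrays of narrowest spread the difference was 0.382 ± 0.0578, which argues against array spread as the source. With the acute phase score as a covariate it was 0.286 ± 0.0724. That fit used a single slope for all diets. The correlation of this list with the acute phase score was 0.826 within casein, 0.792 within dairy and -0.428 within leucine. The fit therefore cannot decide on acute phase state. The list was set against 10000 random lists matched on mean expression and on gene span, taken from the RefSeq gene table. A span was known for 48 of its 49 genes. Their median change (0.238) lay at percentile 99.97, outside the 95% range of -0.139 to 0.0991, which argues against those properties. The percentile treats genes as independent, and the exact permutation test over rats gave p = 0.0857 with n = 4 per diet.

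Urea cycle and amino acid degradation genes were lower with dairy than with casein by 0.71 ± 0.195 (SE). The difference was -0.682 ± 0.252 without the 2 arrays of narrowest spread and -0.676 ± 0.198 with the acute phase score as a covariate, which argues against either as the source. Hepatocyte identity markers differed by -0.0567 ± 0.0997, which argues against a lower share of hepatocytes as the source of a fall of this size. A smaller change of share is not excluded.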

How the results depend on the processing

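With 4 rats per diet, counts of probe sets near the threshold depend on single arrays and on how the spread of the arrays is treated. Mean list differences also move with single arrays, as fatty acid oxidation between leucine and dairy did, from 0.0158 to 0.307. All alternatives below were fixed before the data were examined, apart from the fits without the 2 arrays of narrowest spread, with the acute phase score and with the replicate block over 8 arrays, which were chosen after seeing the data. The cause was not tested for any of the changes.

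Thresholds. At an unadjusted p under 0.05 with a 1.5-fold change, 137 probe sets changed between leucine and casein, 844 between dairy and casein and 457 between leucine and dairy, against 0, 13 and 0 at the adjusted threshold. At an adjusted p under 0.10 there were 0, 52 and 0. For any diet there were 8 at an adjusted p under 0.10 and 1188 at an unadjusted p under 0.05, against 5.

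Normalization and probe sets. Quantile normalization of the deposited values gave 39 probe sets between dairy and casein (34 higher and 5 lower, against 13 higher and 0 lower) and 0 for any diet. Centring each array on its median gave 3 for any diet. All probe sets in the file gave 42 between dairy and casein (37 higher and 5 lower) and 12 for any diet. Without the dimmest probe sets, 5 lists were called between leucine and casein, against 3. After quantile normalization Bckdk, dairy against casein, turned to 0.0183 (from -0.128), Acaca, leucine against dairy, to -0.0806 (from 0.0208) and Pdk4, leucine against dairy, to -0.0253 (from 0.049). With median centring Pck1, leucine against dairy, turned to 0.00488 (from -0.0231). None of these 4 genes passed in any comparison.

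Fits. With trend and robust, 8 probe sets passed between dairy and casein. With array quality weights 1182 did (523 higher and 659 lower), 418 passed for any diet, and 10 lists were called between leucine and casein and 19 between dairy and casein. With weights Fgf21 turned to -0.81 between dairy and casein (from 0.398) and 0.117 between leucine and dairy (from -0.832), and Pck1 to 0.135 between leucine and dairy. With only the 8 arrays of the 2 diets, 6 probe sets passed between dairy and casein. With the replicate block Rpl39 lost its call (adjusted p = 0.0719), 1 probe set, lower, passed between leucine and dairy, 3 passed for any diet, and 6 lists were called between leucine and casein. Over the 3 diets 7 of 12 same-number pairs correlate above 0.1 (range -0.505 to 0.59), and only those of leucine and casein all do.

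Alternatives chosen after seeing the data. With the replicate block over the 8 arrays of leucine and casein, 1 probe set, lower, passed (Acsm5, adjusted p = 0.0362), and 6 lists were called (4 higher and 2 lower, against 2 and 1), with 0 called with an estimated correlation and 0 by fry. It changed no other call. In that comparison 3 of the 8 arrays correlate best with their own number, and 3 of 24 matchings have a mean r as high. Without the 2 arrays of narrowest spread, 164 probe sets passed between dairy and casein (130 higher and 34 lower), and Acaca, leucine against dairy, turned to -0.00201. With the acute phase score as a covariate, 5 lists were called between dairy and casein, against 10, Rps19 and Rpl39 lost their calls (adjusted p = 0.0503 for each), and signs turned for Scd (0.0161) and Pck1 (0.0394) between dairy and casein and for Acaca (-0.0453) and Pdk4 (-0.123) between leucine and dairy.

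List tests. With an estimated correlation 0, 0 and 0 lists were called between leucine and casein, dairy and casein, and leucine and dairy, against 3, 10 and 7. fry called 0, 0 and 0 after adjustment, and the exact permutation test of list scores, not adjusted over the lists, gave 0, 2 and 0 at p under 0.05. After quantile normalization 7 lists were called between dairy and casein (4 higher and 3 lower, against 4 and 6). Calls ended for fatty acid and triglyceride synthesis (-0.394, adjusted p = 0.152), fatty acid oxidation and PPAR-alpha targets (-0.124, 0.188), bile acids (-0.267, 0.0878) and neutrophil markers (0.473, 0.139). Without the dimmest probe sets 7 were called (4 higher and 3 lower), and calls ended for fatty acid and triglyceride synthesis (adjusted p = 0.102), fatty acid oxidation (0.102) and bile acids (0.0864). With trend and robust the call of stellate cell markers ended (0.0521). With the acute phase score calls ended for fatty acid and triglyceride synthesis (0.234), fatty acid oxidation (0.234), bile acids (0.135), neutrophil markers (0.135) and stellate cell markers (0.108), and between leucine and casein for fatty acid and triglyceride synthesis (0.064). Between leucine and dairy the call of fatty acid oxidation ended after quantile normalization (0.0587, adjusted p = 0.353), with median centring (0.0767), without the dimmest probe sets (0.0728) and with the acute phase score (0.181).

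Each array left out. Probe sets numbered 0 to 2 (leucine replicate 2) between leucine and casein, 3 (casein replicate 1) to 237 (casein replicate 4) between dairy and casein, 0 throughout between leucine and dairy, and 0 (casein replicate 1) to 23 (casein replicate 4) for any diet. At an unadjusted p under 0.05 they numbered 355 (casein replicate 1) to 1358 (casein replicate 4) between leucine and casein, 935 (casein replicate 1) to 3244 (casein replicate 4) between dairy and casein, and 695 (leucine replicate 2) to 1443 (dairy replicate 4) between leucine and dairy. Lists numbered 2 (dairy replicate 3) to 8 (leucine replicate 1), 5 (casein replicate 1) to 18 (dairy replicate 1) and 3 (dairy replicate 4) to 14 (dairy replicate 1) in the 3 comparisons. Values moved over 1.5 times between leucine and casein for Nr1h3 (-0.504 to -0.184), Fasn (-1.54 to -0.521), Me1 (-1.49 to -0.368), Acacb (-1.1 to -0.334), Hbb (0.682 to 1.45), Alas2 (0.15 to 1.04), Acaca (-0.859 to -0.211), G6pc1 (-3.33 to -0.76), Insr (-0.371 to -0.147), Bckdk (-0.584 to -0.15), Fgf21 (-1.05 to -0.077) and Pdk4 (-1.16 to -0.192). Between dairy and casein they did for Elovl5 (-1.17 to -0.52), Nr1h3 (-0.599 to -0.252), Acss2 (-1.03 to -0.495), Agpat2 (-0.87 to -0.292), Etfa (-0.845 to -0.394), Slc10a1 (-0.842 to -0.349), Slc27a5 (-0.514 to -0.186), Cyp3a23-3a1 (-0.964 to -0.447), Mmp9 (0.327 to 0.999), S100a9 (0.659 to 2.18), Fpr1 (0.125 to 0.546) and Pdgfrb (0.2 to 0.471), besides the key genes in the report. Between leucine and dairy they did for Abcg5 (0.48 to 1.02), Cyp27a1 (0.278 to 0.627), Abcb4 (0.401 to 0.87), Psmb9 (-1.5 to -0.678), Irf7 (-1.78 to -0.713), Oas1a (-1.12 to -0.315), Ifit1 (-2.49 to -0.239), Fgf21 (-1.43 to -0.168), Cpt1a (0.0735 to 0.633), Cyp7a1 (0.258 to 1.97), Bckdk (-0.447 to -0.0226), Igfbp1 (0.656 to 2.05) and Asns (-1.31 to -0.653). Between leucine and casein the sign turned for Slc4a1 (-0.0136 to 0.576), Scd (-1.24 to 0.175), Cpt1a (-0.455 to 0.104), Pck1 (-0.528 to 0.32), Bcat2 (-0.00918 to 0.0764), Asns (-0.19 to 0.549), Trib3 (-0.0805 to 0.506), Cyp7a1 (-1.65 to 0.275) and Ppargc1a (-0.525 to 0.0102). Between dairy and casein it turned for Scd (-0.979 to 0.38), Pck1 (-0.437 to 0.0833), Igfbp1 (-0.189 to 1.22) and Fgf21 (-0.266 to 0.992). Between leucine and dairy it turned for Acaca (-0.19 to 0.276), Fasn (-0.942 to 0.0947), Scd (-0.861 to 0.497), Pck1 (-0.388 to 0.46), G6pc1 (-2.48 to 0.0919) and Pdk4 (-0.541 to 0.537).

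Correlation of the differences from casein. r was 0.485, -0.0791 with the casein arrays split (-0.353 to 0.0927 over 6 ways), and 0.316 (leucine replicate 3) to 0.696 (casein replicate 4) with each array left out.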

Other observations

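The list of inducible inflammatory genes, its tests and the relations below were chosen after the result was seen, and some of its genes also belong to the acute phase, neutrophil and interferon lists.

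The largest differences between these livers lay between rats of the same diet. The mean log2 signal of 15 inducible inflammatory genes was 6.522, 5.435, 9.714 and 7.795 in casein replicates 1 to 4, 6.469, 9.664, 7.056 and 10.1 in the dairy rats and 5.611, 8.213, 9.98 and 8.809 in the leucine rats. Its pooled within-diet SD was 1.84. Its genes were chosen after the data were seen, so its rank above the lists fixed beforehand is not a test. The next highest were 1.05 for the interferon response, 0.856 for neutrophil markers and 0.772 for fatty acid and triglyceride synthesis. The lowest were 0.103 for cytosolic ribosomal proteins and 0.0845 for the cell cycle list. The transglutaminase Tgm1, the chemokine Cxcl10, the small GTPase Rnd1 and the triglyceride-handling enzyme Pnpla3 had the largest within-diet SDs of single genes (2.85, 2.75, 2.53 and 2.51). Within the casein diet Lcn2 ran from 6.609 to 12.14 and A2m, an acute phase protein of the rat, from 5.976 to 12.24. Within the leucine diet G6pc1, which releases glucose from the liver, ran from 12.54 in replicate 1 to 4.828 in replicate 3, and within the casein diet Pnpla3 ran from 11.39 in replicate 2 to 5.179 in replicate 4. The inflammatory list differed by 0.787 for leucine minus casein, 0.957 for dairy minus casein and -0.17 for leucine minus dairy (exact permutation p = 0.543, 0.514 and 0.943, n = 4 per diet). Of its 15 genes, 15 were higher with leucine and 14 with dairy than with casein, and 7 were higher with leucine than with dairy. These differences lay within the within-diet SD of 1.84, so 4 rats per diet cannot show whether the list differs by diet.

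The variance share of this inflammatory score that followed the replicate number was 0.494 (0.352 to 0.813 with each array left out), which cannot tell a batch that follows the numbers from chance. Without the 2 arrays of narrowest spread the within-diet SD was 2 (1.84 with all arrays, and 1.76 to 2.16 with each array left out), which argues against array spread as the source. The state may come from infection, feeding state at death or handling, and the labels used here do not separate these. Serum acute phase proteins, histology and time of death of the same rats could decide between them.

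Within diets, livers with a higher acute phase score tended to have lower xenobiotic metabolism scores, and the link did not pass adjustment over the 8 relations tried. Over 12 deviations from the diet means, r was -0.759 (permutation p = 0.0139, adjusted 0.111) and rho -0.769 (permutation p = 0.0123, adjusted 0.0678), and r was -0.58 without the 2 rats farthest out. The relation to fatty acid and triglyceride synthesis had r = -0.601 and rho = -0.727, and that to the unfolded protein response r = 0.645 and rho = 0.657 (permutation, adjusted p of r 0.125 for each). For the circadian clock, bile acids and glycolysis r was -0.593, -0.577 and -0.517. The weakest over all 12 rats were those to the urea cycle list (r = -0.358) and cytosolic ribosomal proteins (r = 0.359; permutation, adjusted p of r 0.342 for each). For the ribosomal list the diets differed, with r of 0.826 within casein, 0.792 within dairy and -0.428 within leucine. Its r was 0.661 without the 2 rats farthest out. A larger cohort with an inflammatory marker measured in serum would show whether these relations hold.

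Mitochondrial ribosomal proteins were looked at beside the cytosolic ones, without a test between the lists. The mitochondrial list (57 genes) differed by -0.0628 between dairy and casein (exact permutation p = 0.6, n = 4 per diet, against 0.0857 for the cytosolic list), by -0.0201 between leucine and casein (p = 0.857) and by 0.0428 between leucine and dairy (p = 0.657). Of 260 probe sets of 73 cytosolic ribosomal protein genes, 212 were higher with dairy and 183 with leucine than with casein, with median differences of 0.411 and 0.181. Array probes for these genes also match many genomic copies, so sequencing of the same RNA or a quantitative PCR of Rps15a with junction-spanning primers would test the change.

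A hypothesis for the dairy diet is a lower supply of amino acids to the liver, which was not tested here. It rests on the lower urea cycle and amino acid degradation list and the higher ATF4 list, whose camera adjusted p were 0.416 and 0.494 with an estimated correlation. It does not account for the higher cytosolic ribosomal protein genes, which gave all 13 probe sets called with dairy and differed as a list by 0.301. The signals of mTORC1 and amino acid sensing genes differed by -0.0652, and the activity of mTORC1 was not measured. Protein supplied 10% of energy in each diet. The ATF4 list, with a difference of 0.236 without dairy replicate 4 and 0.379 with all arrays, may depend on 1 rat. Amino acid concentrations in portal blood, liver urea output and phosphorylated eIF2alpha in rats fed the 3 diets would test the hypothesis.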
